A study of Homo sapiens with 9 samples.

How the data were processed

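RNA sequencing of 9 libraries was analysed, 3 each from MDA-MB-231 cells with a control vector, with ERβ1, and with ERβ1 and the ligand CLI, all given doxycycline. Per the labels' protocols, total RNA was extracted with Trizol and columns with DNase treatment, stranded mRNA libraries were made with a TruSeq kit, and single reads of 101 cycles came from 1 lane of a NovaSeq instrument. The labels number the cell line from MDA-MB-231 upward from library to library, while the growth protocol names MDA-MB-231 alone, and the count columns call the controls wild type; all libraries were read as MDA-MB-231 and the columns were matched to the groups by treatment and replicate number. Per the submitters' processing notes, bcl2fastq 2.20, FastQC, Trimmomatic 0.38, Salmon 1.2.1, R 4.0.2 and edgeR 3.30.3 were used with the GRCh38 build. Their settings, the annotation release and the dose of CLI are not given in the sources used here.

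The deposited estimated counts per gene cover 60240 Ensembl gene IDs, with no normalization stated. The authors also deposited log2 CPM for 18934 genes, with library sizes scaled by TMM per the labels. Reads were not analysed here. Positions were taken from GENCODE release 29 (GRCh38), which held 58064 of the gene IDs.

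The estimated counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, which left 17058, library sizes were scaled by TMM, and all 9 libraries entered 1 quasi-likelihood fit with 1 coefficient per group. The 3 comparisons were ERβ1 cells with control cells, ERβ1 cells with CLI with ERβ1 cells, and ERβ1 cells with CLI with control cells. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. A change of at least 2-fold means an absolute log2 fold change of at least 1. CPM are counts per 1e6 with TMM-scaled library sizes, given as mean and SD. The SE of a log2 fold change is its size divided by the square root of the F of the test. Groups of 3 and 3 cannot give an exact permutation p under 0.1, so single genes rest on the model. Where all libraries of a group held 0 counts, a bound was given against a floor of 3 counts per library, which covers counting error only. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

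Total counts were 46676214, 44297885 and 43487559 in control libraries, 43162611, 55387538 and 39902456 in ERβ1 libraries and 43023424, 50106054 and 43790287 with CLI. Mitochondrial transcripts took 7.13, 7.56 and 7.65% of the counts in the 3 groups on average. No libraries were identical, and replicates differed by more than counting noise (chi-square per gene of 11.8 to 22.9 between libraries of a group).

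Before the data were examined, the tests, the lists, the alternatives and the rule for named genes were written down. The rule names ESR2 first, then the 10 largest rises and 10 largest falls of each of the first comparisons, and 5 and 5 of the third, among called genes with a mean of at least 2 CPM, non-overlapping groups and a symbol that is not a clone, LOC, LINC, antisense or read-through name. From each list it names up to 4 called members with the smallest adjusted p. Results for a few genes are not reported here. The 26 lists held steroid receptors, oestrogen-responsive genes, mitosis, DNA replication, p53 and arrest, mesenchymal, epithelial, invasion and metastasis, cystatins, TGF-beta, YAP/TAZ, NF-kB and cytokines, interferon, cholesterol, fatty acids, unfolded protein and integrated stress response, hypoxia and glycolysis, respiratory chain, aryl hydrocarbon receptor, NRF2, Wnt and immediate early genes, markers of luminal breast epithelium, fibroblasts and blood cells, and mitochondrially encoded transcripts. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with the correlation estimated per list and the self-contained test fry stand beside it. Members were also adjusted over their list alone.

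The alternatives were RLE and upper quartile scaling, TMM without ESR2, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-trend on the deposited log2 CPM, the 6 libraries compared alone, the replicate number of the titles as a block, and each library left out in turn. Added after the data were seen were receptor libraries numbered 1 and 3 alone, a block within the 6 libraries compared, genes of shifted 10 Mb windows left out, and 9 further gene families. Residuals of 12574 genes were correlated between same-numbered libraries, with the numbers taken from the titles, to see whether the numbers pair the samples. For ERβ1 cells with and without CLI the correlations were 0.158, 0.441 and 0.183, each over 0.1, so by the rule these counted as pairs. The main counts, fold changes and list tests nevertheless come from the fit without a block. The block value is given beside the count of genes and where it changes the call of a named gene. Libraries numbered 1 and 3 correlated about as much with each other (0.178 and 0.161), and those numbered 2 stood apart, so these correlations do not show 3 distinct pairs. Some genes did differ between numbers 1 and 3 alike in both ERβ1 groups. SIPA1L3 stood at 136 and 463 CPM in ERβ1 replicates 1 and 3, and at 137 and 339 CPM in those with CLI. For ERβ1 and control cells they were -0.0909, -0.0673 and 0.0361, and for cells with CLI and control cells 0.0452, 0.00291 and 0.0551.

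The fit was tested on simulated data with 50 genes changed at each fold. For ERβ1 and control cells it recovered 18, 52, 70 and 84% of changes of 1.25, 1.5, 2 and 4-fold, and 5.08% of its 118 calls were false. For cells with and without CLI it recovered 20, 44, 76 and 84%, and 8.2% of its 122 calls were false. Simulations of unchanged groups (20) gave the covariances expected from shared libraries, but with almost no genes called they give no such value for overlaps of calls. Windows of 10 Mb with at least 15 genes were scored by the median log2 fold change, with ESR2 left out, and taken as shifted past 0.15 in both comparisons with control.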

Results

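Messenger RNA was sequenced from 9 cultures of MDA-MB-231, an established human basal-type breast cancer cell line that lacks high expression of the classical oestrogen receptor and is used as a model of triple negative breast cancer. The cells carried a lentiviral vector whose expression is switched on by doxycycline. The vector encoded GFP and luciferase alone (control cells) or together with isoform 1 of oestrogen receptor beta (ERβ1 cells), the receptor encoded by ESR2. All cells received doxycycline at 100 ng/ml for 3 days, and 1 group of ERβ1 cells also received the ligand CLI for 24 h, so that the series held 3 groups of 3 libraries. The libraries held 39902456 to 55387538 estimated counts each, and 17058 of 60240 annotated genes had enough counts to be tested. No control cells received CLI, so ligand effects that do not need the receptor cannot be separated here. The labels do not say whether replicates were separate cultures or passages, and p-values measure the spread between these samples only. Oestrogen receptor beta status by protein, growth and metastasis were not analysed here.

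The transduced gene was measured first. ESR2 (ENSG00000140009, chromosome 14, 64084232 to 64338112, minus strand, GRCh38) stood at 0.137 ± 0.00454 CPM in control cells (SD, n = 3), a total of 18 counts over the 3 libraries. It reached 117 ± 1.51 CPM in ERβ1 cells and 84.2 ± 3.09 CPM in ERβ1 cells with CLI (SD, n = 3 each). The log2 fold change over control was 9.71 ± 0.07 (SE) in ERβ1 cells and 9.23 ± 0.07 with CLI (edgeR adjusted p = 6.45e-12 and 5.22e-12), so each library matched its label as control or receptor cells. These SE were derived from the test and are too small to hold the counting error of the 18 control counts. With limma-trend on the deposited log2 CPM the fold changes were 9.35 and 8.87. ESR2 is no check of which receptor libraries received CLI. With CLI, ESR2 mRNA was lower than in ERβ1 cells without CLI by a log2 fold change of -0.48 ± 0.04 (edgeR adjusted p = 0.000363). Of the other receptors listed beforehand, the glucocorticoid receptor gene NR3C1 stood at 148 ± 4.9 CPM in control and 148 ± 0.753 CPM in ERβ1 cells, a log2 fold change of -0.01 (edgeR adjusted p = 0.907). The progesterone receptor gene PGR was too low to be tested, with at most 0.12 CPM in any library.

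The first comparison set ERβ1 cells without added ligand against control cells. Effects of the receptor cannot be told apart in it from other differences between the transduced cell populations. ERβ1 cells had far more RNA than control cells for the cystatins CST1, CST2 and CST4, which are secreted cysteine protease inhibitors. The abundant cystatin gene CST3 rose far less. RNA for complement C3, cyclooxygenase 2 (PTGS2) and the oestrogen-responsive genes GREB1 and PDZK1 was also far higher. ERβ1 cells had less RNA for the metalloprotease ADAMTS1, the axon guidance receptor ROBO1 and the chemokine receptor CXCR4. Groups of inflammatory, interferon-stimulated and TGF-beta responsive genes were higher, while NRF2 targets, stress response genes and mitotic genes were lower. With an estimated correlation the interferon and TGF-beta lists kept their calls (limma camera adjusted p = 0.0183 and 0.049), and the inflammatory, NRF2, stress response and mitotic lists did not (0.135, 0.0765, 0.0765 and 0.38). Of 17058 genes tested with edgeR's quasi-likelihood test, 3645 changed at an adjusted p under 0.05, 1825 upward and 1820 downward. At least a 2-fold change was seen in 626 of them, 464 higher and 162 lower. All 3 libraries of one group lay on one side of the other group's for 6747 genes, where chance gives 10% of the genes tested, or 1705.8.

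After ESR2 the gene with the largest rise among those named with a mean of at least 2 CPM was C3 (chromosome 19, 6677704 to 6730562), the central complement component, which went from 3.08 ± 0.41 to 42.1 ± 5.96 CPM (SD, n = 3 each; log2 fold change 3.78, SE 0.13, edgeR adjusted p = 5.98e-07). CST1 (chromosome 20, 23747553 to 23751268) rose from 5.05 ± 0.38 to 59.1 ± 2.56 CPM, a log2 fold change of 3.55 (edgeR adjusted p = 4.6e-09). PTGS2, which makes prostaglandins from arachidonic acid, rose from 0.888 ± 0.165 to 8.26 ± 1.06 CPM (log2 fold change 3.21). GREB1 (chromosome 2, 11482341 to 11642788), a cofactor of oestrogen receptors, rose from 0.827 ± 0.208 to 5.14 ± 0.202 CPM, a log2 fold change of 2.64 (edgeR adjusted p = 1.03e-05). Rises between log2 2.73 and 3.13 were measured for the placental alkaline phosphatase gene ALPP, GASK1B, the matricellular gene CCN5, the scaffold gene PDZK1 and the fatty acid binding protein gene FABP3. FBXL16 was also named by the rule (log2 fold change 3.57, edgeR adjusted p = 0.0315), but ERβ1 replicate 1 alone set its size, with 49.9 CPM against 4.19 and 3.45 CPM in the other ERβ1 libraries. Without that library the log2 fold change of FBXL16 was 1.25, and leaving out control replicate 1, 2 or 3 ended the call, with adjusted p of 0.0938, 0.1 and 0.0889.

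Among the largest falls named by the rule, ADAMTS1 (chromosome 21, 26835747 to 26845409), a secreted protease that cleaves proteoglycans, fell from 27.6 ± 4.46 to 0.999 ± 0.643 CPM (SD, n = 3 each; log2 fold change -4.80, edgeR adjusted p = 3.35e-05), and its fall was larger, -5.44, without ERβ1 replicate 1. ROBO1 fell from 8.13 ± 2.52 to 0.239 ± 0.122 CPM (log2 fold change -5.03, edgeR adjusted p = 0.000776) and LYPD5, a surface protein gene, from 12.8 ± 0.79 to 0.585 ± 0.149 CPM. The carboxypeptidase gene CPVL, the tight junction gene TJP3, the cancer-testis gene PAGE5, the GTPase gene RHOJ and the semaphorin gene SEMA5A fell by 4.12, 3.47, 3.23, 2.40 and 2.33 on the log2 scale. The fall of TJP3 was -4.46 without ERβ1 replicate 3. A lincRNA known by the clone name CU634019.2, kept because it escaped the written name patterns, stood at 4.38 ± 0.994 CPM in control and 0.0476 ± 0.0824 CPM in ERβ1 cells (log2 fold change -6.23, edgeR adjusted p = 0.0153). Its call ended without ERβ1 replicate 1 or 3, with adjusted p of 0.0539 and 0.0561, and its fold rested on 8 counts, being -10.60 without ERβ1 replicate 2.

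**Figure D1:**
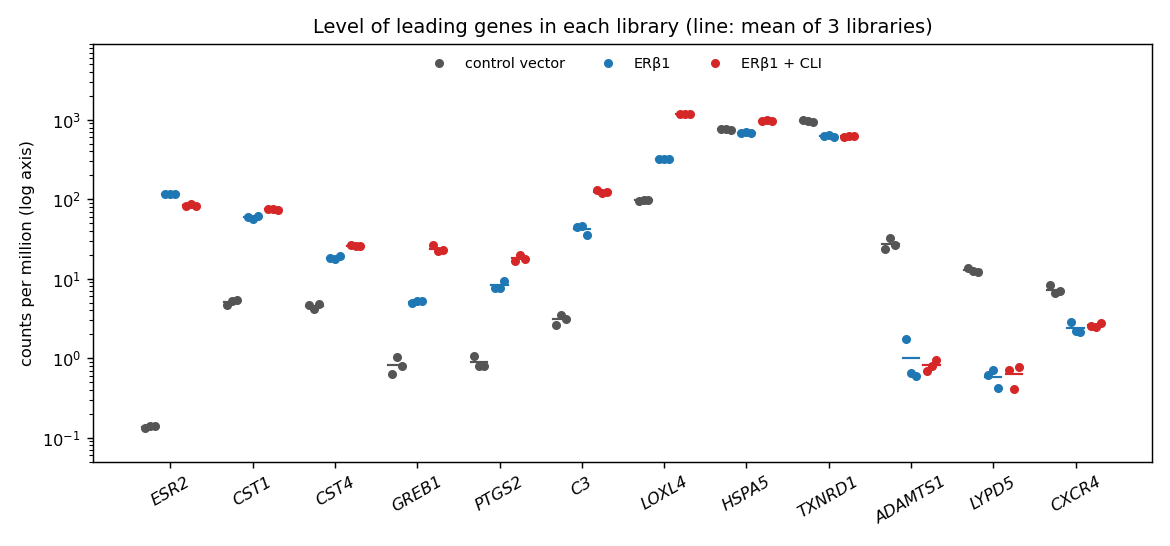
CPM (log axis) of 12 genes in each library, with dots for single libraries and lines for the means of 3. ESR2 stood at 0.137 CPM in control cells and 117 CPM in ERβ1 cells, and LOXL4 at 321 CPM in ERβ1 cells and 1185 CPM with CLI.

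The lists of cystatins and of oestrogen-responsive genes were called higher, and the cystatin list alone of these kept its call with an estimated correlation. Of 8 cystatin genes tested, 7 were higher and 0 lower, also 7 when adjusted over the list alone, where 1 was lower (limma camera adjusted p = 2.34e-08, and adjusted p = 0.0183 with an estimated correlation). CST4 rose from 4.56 ± 0.327 to 18.3 ± 0.756 CPM and CST2 from 0.718 ± 0.127 to 3.66 ± 0.0516 CPM (SD, n = 3 each). CST3, the abundant cystatin C gene, rose from 171 ± 3.22 to 216 ± 1.25 CPM. CST1, CST2 and CST4 lie side by side on chromosome 20 and are close in sequence, so the split of reads between them is uncertain. The median over the list was 1.40 on the log2 scale, and also 1.40 with CST5, which had 0 counts in control cells, set at its lower bound. Of 16 oestrogen-responsive genes, 6 were higher and 1 lower, and 7 were higher when adjusted over the list alone (limma camera adjusted p = 0.00289). That call was lost with adjusted p = 0.0669 with an estimated correlation. IGFBP4, which binds insulin-like growth factors, rose from 672 ± 22.6 to 1069 ± 30.5 CPM. KRT13 had 0 counts in all 3 control libraries and 29 counts in ERβ1 cells, at least 3.1-fold higher against a floor of 3 counts per library.

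The lists of inflammatory, interferon and TGF-beta genes were called higher, and those of interferon and TGF-beta genes kept their calls with an estimated correlation. Of 20 NF-kB targets and cytokines, 15 were higher and 0 lower, 17 when adjusted over the list alone (limma camera adjusted p = 1.26e-08, with a median log2 fold change of 0.54), but adjusted p = 0.135 with an estimated correlation. The interleukin gene IL1B rose from 6.47 ± 1.06 to 16.9 ± 0.786 CPM and the neutrophil chemokine gene CXCL8 from 12.7 ± 2.39 to 25.1 ± 1.83 CPM (SD, n = 3 each). Of 22 interferon-stimulated genes, 13 were higher and 0 lower, 17 adjusted over the list alone (limma camera adjusted p = 4.83e-08, and adjusted p = 0.0183 with an estimated correlation). IFIT2 rose from 18.3 ± 0.573 to 31.1 ± 0.6 CPM and OASL by a log2 fold change of 1.32. Of 16 TGF-beta target genes, 9 were higher and 0 lower, 10 adjusted over the list alone with 1 lower (limma camera adjusted p = 0.000458, and adjusted p = 0.049 with an estimated correlation). PMEPA1 rose by 1.06, LTBP2 by 0.82 and the inhibitory gene SKIL by 0.59 on the log2 scale. LTBP2 lies in a stretch of chromosome 14 in which neighbouring genes were higher, described further on. Of 21 immediate early genes, 10 were higher and 2 lower, 10 and 3 adjusted over the list alone (limma camera adjusted p = 0.00289, but adjusted p = 0.223 with an estimated correlation). EGR1 rose from 21.3 ± 0.641 to 83.2 ± 7.33 CPM and the phosphatase gene DUSP1 from 15.6 ± 0.427 to 35.5 ± 0.94 CPM.

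The lists of redox defence, stress response and mitotic genes were called lower, but none kept its call with an estimated correlation. Of 20 NRF2 targets, 12 were lower and 2 higher, 13 and 2 adjusted over the list alone (limma camera adjusted p = 0.000168, but adjusted p = 0.0765 with an estimated correlation). TXNRD1, a thioredoxin reductase, fell from 969 ± 15.9 to 623 ± 17.2 CPM, SLC7A11, the cystine importer, from 323 ± 4.72 to 234 ± 5.64 CPM and NQO1 from 297 ± 6.2 to 203 ± 5.37 CPM (SD, n = 3 each). Of 20 unfolded protein and integrated stress response genes, 12 were lower and 1 higher, the same counts adjusted over the list alone (limma camera adjusted p = 0.000986, but adjusted p = 0.0765 with an estimated correlation). The members with the smallest adjusted p were PSAT1 and ASNS, which make serine and asparagine and fell by 0.47 and 0.39 on the log2 scale, and SESN2 and TRIB3, which fell by 0.83 and 0.36. Of 25 mitotic genes, 8 were lower and 0 higher, 9 adjusted over the list alone (limma camera adjusted p = 0.00129, but adjusted p = 0.38 with an estimated correlation). Their changes were small: CDC20 fell from 239 ± 5.75 to 183 ± 9.71 CPM, KIF23 and CDK1 fell by 0.21 and 0.19 on the log2 scale, and the median of the list was -0.09.

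Markers of luminal breast epithelium, listed to look for other cells, were lower in 4 of 9 cases and higher in 0, 5 adjusted over the list alone (limma camera adjusted p = 0.00129, but adjusted p = 0.0669 with an estimated correlation). AGR2 had 116 counts over the control libraries and 0 in ERβ1 cells, at least 13.5-fold lower against a floor of 3 counts per library, and SPDEF fell from 3.05 ± 0.363 to 0.433 ± 0.244 CPM (SD, n = 3 each). The list's median was -0.22, also with AGR2 at its bound. Of 4 fibroblast markers tested, LUM rose from 0.0453 ± 0.0214 to 0.311 ± 0.0713 CPM and COL1A1 by 0.65 on the log2 scale (edgeR adjusted p = 0.0456). The call of COL1A1 was lost without 7 of the 9 libraries in turn, control replicates 2 and 3, each ERβ1 replicate and ERβ1 with CLI replicates 1 and 2, with an adjusted p of up to 0.135. Of 4 blood cell markers tested, LYZ rose from 0.0613 ± 0.0277 to 0.353 ± 0.0358 CPM. Neither marker list was called (limma camera adjusted p = 0.232 and 0.184), with counts of 2 and 1 higher adjusted over the list alone.

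Genes of invasion, epithelial state and mesenchymal state moved both ways. Of 21 matrix-degrading and metastasis genes, 9 were higher and 4 lower, 10 and 6 adjusted over the list alone (limma camera adjusted p = 0.147). CXCR4 fell from 7.28 ± 0.87 to 2.39 ± 0.377 CPM, while LTBP1 rose from 33.8 ± 2.94 to 56.3 ± 0.937 CPM (SD, n = 3 each). Of 16 mesenchymal genes, 7 were higher and 5 lower, 8 and 6 adjusted over the list alone (limma camera adjusted p = 0.232). The transcription factor gene SNAI1 rose from 0.843 ± 0.147 to 5.1 ± 0.699 CPM, whereas vimentin (VIM) fell from 3041 ± 110 to 2460 ± 43.6 CPM and S100A4 fell by 0.59 on the log2 scale. Of 16 epithelial genes, 3 were higher and 3 lower, 4 and 4 adjusted over the list alone (limma camera adjusted p = 0.651). CDH1, the E-cadherin gene, rose from 0.12 ± 0.0758 to 1.33 ± 0.541 CPM, a low level, and CLDN1 from 8.31 ± 0.458 to 12.8 ± 0.782 CPM. Of 16 YAP/TAZ targets, 4 were higher and 5 lower, 6 and 5 adjusted over the list alone (limma camera adjusted p = 0.971), and the list's median of -0.02 and mean of 0.01 differed in sign. Of 10 Wnt targets, 2 were lower, DKK1 by -0.52 and LEF1 by -1.90 on the log2 scale, also 2 adjusted over the list alone (limma camera adjusted p = 0.458).

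Metabolic and housekeeping groups changed little as groups. Of 22 hypoxia and glycolysis genes, 9 were higher and 2 lower, the same adjusted over the list alone (limma camera adjusted p = 0.0207, but adjusted p = 0.223 with an estimated correlation and 0.0517 without control replicate 3 or without ERβ1 replicate 2). EGLN3 rose by 0.96 and NDRG1 by 0.24 on the log2 scale, while the glucose transporter gene SLC2A1 and the enolase gene ENO1 fell by 0.41 and 0.46. Of 16 fatty acid genes, 6 were lower and 2 higher, 7 and 3 adjusted over the list alone (limma camera adjusted p = 0.0548), with the desaturase gene SCD falling by 0.69 and FADS1 by 0.43. Of 25 cholesterol genes, 6 were lower and 2 higher, the same adjusted over the list alone (limma camera adjusted p = 0.429), and HMGCS1 rose by 0.39 while INSIG1 fell by 0.32. Of 25 nuclear-encoded respiratory genes, 6 were lower and 1 higher, the same adjusted over the list alone (limma camera adjusted p = 0.0675), among them NDUFV2 at -0.28 and SDHB at -0.27. Of 25 replication genes, 4 were lower and 1 higher, the same adjusted over the list alone (limma camera adjusted p = 0.184), with TYMS at -0.41 and MCM7 at -0.22. Of 20 p53 and arrest genes, 4 were lower and 2 higher, the same adjusted over the list alone (limma camera adjusted p = 0.462), with GADD45A at -0.65 and BTG2 at 0.78. Of 8 aryl hydrocarbon receptor targets, 2 were higher and 2 lower, the same adjusted over the list alone (limma camera adjusted p = 0.698), with CYP1B1 at 0.28 and NQO1 at -0.55, and the median of 0.04 and mean of -0.18 differed in sign. Of 13 mitochondrially encoded transcripts, 3 were higher and 1 lower, the same adjusted over the list alone (limma camera adjusted p = 0.218), with MT-CO1 at -0.13 and MT-ND3 at 0.20. Among 5 steroid receptor genes tested, ESR2 was the 1 that changed, also adjusted over the list alone (limma camera adjusted p = 0.0745), and the list's median of -0.01 and mean of 1.97 differed in sign.

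Neighbouring genes moved together in parts of the genome, a pattern examined after the calls were seen. Of 252 windows of 10 Mb, 17 had a median log2 fold change of at least 0.15 in size and in the same direction in both groups of ERβ1 cells against control. Genes on chromosome 14 between 50 and 80 Mb were higher in 3 windows, with medians of 0.17, 0.31 and 0.29 in ERβ1 cells. Genes in 14 windows were lower, among them those of chromosome 1 between 0 and 30 Mb, with medians of -0.27, -0.29 and -0.28, and further windows on chromosomes 1, 6, 8, 13 and 18. Averaged over the 17 windows in the direction of the shift, libraries stood at 0.00124 ± 0.00579 in control cells, 0.232 ± 0.00351 in ERβ1 cells and 0.233 ± 0.00609 with CLI (SD, n = 3 each). The windows were picked for this difference, so these averages are no test of it. The windows held 5.8% of the genes tested and 12% of the genes called in ERβ1 cells, 436 genes. Among the genes named above, LTBP2 and RHOJ lie in the windows that were higher, though RHOJ itself was lower, at -2.40 on the log2 scale. The locus of the transduced gene ESR2 lies there too, but ESR2 was left out of the medians. SESN2, ENO1, GADD45A, SDHB, NDUFV2 and TYMS lie in windows that were lower. With the genes of these windows left out, 3122 genes were called, 3112 of them also among the 3645.

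**Figure D2:**
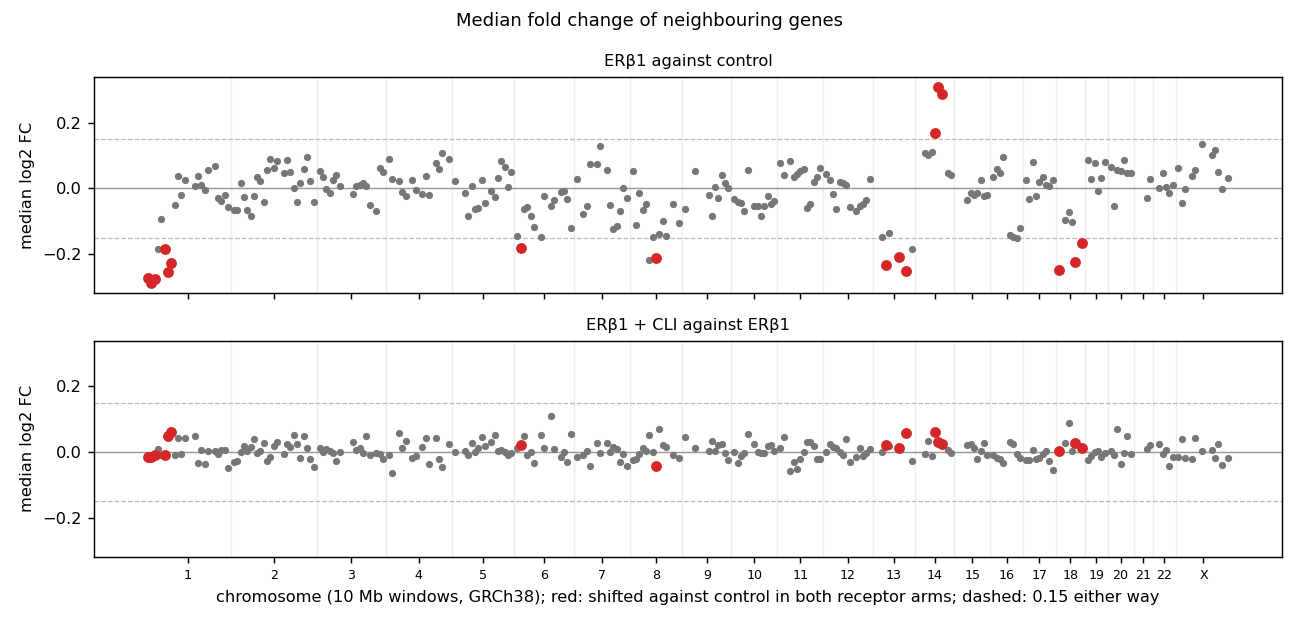
Median log2 fold change of the genes in each of 252 windows of 10 Mb along the chromosomes (GRCh38), for ERβ1 cells against control (upper panel) and ERβ1 cells with CLI against ERβ1 cells (lower panel). The 17 windows in red had medians of at least 0.15 in size against control in both ERβ1 groups, and in the lower panel no window exceeded 0.11.

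The second comparison asked what 24 h of the ligand CLI adds in cells that already express ERβ1. CLI raised a small set of genes, led among those named with a mean of at least 2 CPM by the secreted protein gene OLFML3, GREB1, the inhibin subunit gene INHBB and the lysyl oxidase gene LOXL4. Of 20 unfolded protein and integrated stress response genes, 5 were higher and 15 were not called. Oestrogen-responsive genes and cystatins rose further, while interferon-stimulated genes were lower as a group, with 2 of 22 called. With an estimated correlation the oestrogen-responsive list kept its call (limma camera adjusted p = 0.0425), and the cystatin, interferon and stress response lists did not (0.0617, 0.106 and 0.0576). Of 17058 genes, 251 changed (edgeR's quasi-likelihood test at an adjusted p under 0.05), 178 upward and 73 downward, and 43 changed at least 2-fold, 42 of them upward. The groups did not overlap for 3206 genes, where chance gives 10%, or 1705.8. The count was sensitive to single libraries, to pairing and to the method. DESeq2 called 583 genes. Receptor libraries numbered 1 and 3 alone gave 72, and the block within the 6 libraries compared gave 66. The count was 117, 123 and 119 without ERβ1 replicate 1, 2 and 3, and 153, 150 and 114 without ERβ1 with CLI replicate 1, 2 and 3. It was 136, of which 129 were among the 251, with the replicate number as a block, which the correlation between same-numbered libraries of these groups called for. The count of 2-fold changes was 27 without ERβ1 replicate 3.

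LOXL4, which cross-links collagen, rose from 321 ± 0.152 to 1185 ± 13.3 CPM (SD, n = 3 each), a log2 fold change of 1.89 with an SE of 0.02 (edgeR adjusted p = 1.1e-09). OLFML3 rose from 2.09 ± 0.219 to 10.4 ± 0.453 CPM (log2 fold change 2.32, edgeR adjusted p = 0.000122) and GREB1 from 5.14 ± 0.202 to 23.9 ± 2.18 CPM (log2 fold change 2.22, edgeR adjusted p = 9.47e-05). INHBB, at 2.11 ± 0.151 CPM in control and 1.82 ± 0.11 CPM in ERβ1 cells, rose to 6.75 ± 0.694 CPM with CLI (log2 fold change 1.89, edgeR adjusted p = 0.000122). C3 rose again, to 124 ± 6.57 CPM (log2 fold change 1.56, edgeR adjusted p = 0.000216). FABP3, CCN5 and the transporter gene SLC47A1 rose by 1.65, 1.63 and 1.49 on the log2 scale. SLITRK4 and PDZK1 rose by 1.74 and 1.32 (edgeR adjusted p = 0.011 and 0.0133), but single left-out libraries ended both calls, with adjusted p of up to 0.0614 and 0.0703, both without ERβ1 replicate 2. With the replicate block within the 6 libraries compared, a fit with few residual degrees of freedom added after the data were seen, SLITRK4, FABP3 and SLC47A1 were not called in edgeR (adjusted p = 0.059, 0.0551 and 0.112).

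Falls with CLI were smaller and less firm. SERPINB2, a plasminogen activator inhibitor gene, fell from 9.62 ± 0.145 to 5.97 ± 0.268 CPM (SD, n = 3 each; log2 fold change -0.69, edgeR adjusted p = 0.00287) and PTGES, a prostaglandin E synthase gene, from 31.4 ± 1.95 to 22 ± 0.906 CPM (log2 fold change -0.51, edgeR adjusted p = 0.00799). These 2 of the 10 largest falls kept their calls with each library left out in turn and with the block over all 9 libraries, but not with the block within the 6 libraries compared (edgeR adjusted p = 0.0809 and 0.0883), which ended the calls of all 10. The other 8 did not keep theirs with each library left out. Each of those 8 calls ended without most single libraries of the ERβ1 groups, with the highest adjusted p without ERβ1 with CLI replicate 3 for SEMA4D (0.161), B3GALT5 (0.144), MUSK (0.137), RPL13AP20 (0.137) and FGF1 (0.116), without ERβ1 replicate 1 for CIITA (0.124) and KCTD4 (0.103), and without ERβ1 replicate 2 for TNC (0.101). CIITA, the class II transactivator gene, fell from 16.1 ± 4.41 to 7.39 ± 1.24 CPM (edgeR adjusted p = 0.034, and 0.0722 with the replicate block). SEMA4D, B3GALT5, KCTD4, TNC and MUSK fell by 0.87, 0.74, 0.72, 0.60 and 0.60 on the log2 scale, and with the replicate block in edgeR their adjusted p were 0.0932, 0.0753, 0.0715, 0.0871 and 0.113. FGF1 fell by 0.67 (edgeR adjusted p = 0.0312). RPL13AP20 fell by 0.60 (edgeR adjusted p = 0.1 with the replicate block), and as a processed pseudogene that can share reads with its parent gene it is uncertain.

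The lists of oestrogen-responsive genes and of unfolded protein and integrated stress response genes had the smallest p after CLI. Of 16 oestrogen-responsive genes, 6 were higher and 0 lower, the same adjusted over the list alone (limma camera adjusted p = 5.68e-06, and adjusted p = 0.0425 with an estimated correlation). IGFBP4 rose from 1069 ± 30.5 to 1392 ± 48.4 CPM, the cathepsin D gene CTSD from 839 ± 44.6 to 1136 ± 24.4 CPM and KRT13 from 0.213 ± 0.0461 to 2.0 ± 0.263 CPM (SD, n = 3 each). Of 20 unfolded protein and integrated stress response genes, 5 were higher and 0 lower, 10 and 1 adjusted over the list alone (limma camera adjusted p = 4.35e-06, but adjusted p = 0.0576 with an estimated correlation). The members that rose were folding and quality control genes of the endoplasmic reticulum. HSPA5 went from 686 ± 14.2 to 976 ± 23.3 CPM, HSP90B1 from 950 ± 12.6 to 1353 ± 35.5 CPM, PDIA4 from 249 ± 2.46 to 344 ± 6.75 CPM and CALR from 1176 ± 19.5 to 1476 ± 22.5 CPM, with edgeR adjusted p of 7.75e-05, 8.74e-05, 9.47e-05 and 0.00252. Of 8 cystatins, 3 were higher and 0 lower, 5 and 1 adjusted over the list alone (limma camera adjusted p = 0.00072, but adjusted p = 0.0617 with an estimated correlation). CST4 rose from 18.3 ± 0.756 to 25.9 ± 0.513 CPM (edgeR adjusted p = 0.00656, and 0.0674 with the block within the 6 libraries), and CST1 and CST5 rose by 0.34 and 1.66 on the log2 scale, with adjusted p of 0.0542 and 0.0804 in edgeR with the replicate block, and of up to 0.0795 without ERβ1 replicate 2 and 0.0745 without ERβ1 replicate 1.

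Further groups moved slightly. Of 22 interferon-stimulated genes, 2 were lower and 0 higher, 5 and 1 adjusted over the list alone (limma camera adjusted p = 0.00285, but adjusted p = 0.106 with an estimated correlation). IFIT2 fell from 31.1 ± 0.6 to 23 ± 0.407 CPM (SD, n = 3 each; edgeR adjusted p = 0.00263, and 0.0674 with the block within the 6 libraries), and IFIT1 by -0.35 on the log2 scale, with an adjusted p of 0.0722 in edgeR with the replicate block. Of 16 TGF-beta targets, 3 were higher and 1 lower, 6 and 1 adjusted over the list alone (limma camera adjusted p = 0.0226, but adjusted p = 0.117 with an estimated correlation). That call also ended without ERβ1 replicate 1 or 2 or ERβ1 with CLI replicate 1 or 2, with adjusted p of 0.0611, 0.0668, 0.0623 and 0.0661. SMAD7, PMEPA1 and SKIL rose by 0.35, 0.31 and 0.27 and TGFB2 fell by 0.27, with adjusted p of 0.0871, 0.0646, 0.0961 and 0.0804 in edgeR with the replicate block. Of 20 NRF2 targets, FTH1 was the 1 called, higher by 0.14 (edgeR adjusted p = 0.0449, and 0.0576 with the replicate block), and 7 were higher adjusted over the list alone (limma camera adjusted p = 0.00072, but adjusted p = 0.117 with an estimated correlation). Of 16 YAP/TAZ targets, TGFB2 and RBMS3 were lower and 0 higher, 5 and 1 adjusted over the list alone (limma camera adjusted p = 0.0196, but adjusted p = 0.401 with an estimated correlation, 0.0722 without ERβ1 replicate 2 and 0.117 without ERβ1 with CLI replicate 3). RBMS3 stood at -0.28 on the log2 scale, with an adjusted p of 0.0722 in edgeR with the replicate block. Of the genes in this paragraph all but IFIT2 also lost their calls without single libraries, with the highest adjusted p without ERβ1 with CLI replicate 3 for IFIT1 (0.138), SMAD7 (0.166) and TGFB2 (0.11), without ERβ1 replicate 2 for SKIL (0.125) and RBMS3 (0.119), and without ERβ1 replicate 3 for PMEPA1 (0.0928) and FTH1 (0.148).

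Replication and respiratory genes were lower as groups with 0 single genes called in either list of 25, also 0 adjusted over the list alone. For replication genes the median was -0.06 (limma camera adjusted p = 0.0196, but adjusted p = 0.492 with an estimated correlation), and the call ended without ERβ1 replicate 2 or ERβ1 with CLI replicate 1 or 3, with adjusted p of 0.129, 0.0902 and 0.125. For respiratory genes the median was -0.04 (limma camera adjusted p = 0.0485, but adjusted p = 0.492 with an estimated correlation). That call ended without control replicate 1 or 2, ERβ1 replicate 1 or 2, or ERβ1 with CLI replicate 1 or 3, with adjusted p of 0.0583, 0.0557, 0.197, 0.0668, 0.0545 and 0.266. Among 5 steroid receptor genes, ESR2 was the 1 that changed, also adjusted over the list alone (limma camera adjusted p = 0.00592, but adjusted p = 0.117 with an estimated correlation). This call ended without control replicate 1 or 2, ERβ1 replicate 1 or 3, or ERβ1 with CLI replicate 3, with adjusted p of 0.0604, 0.0557, 0.0611, 0.152 and 0.155, settings in which ESR1 entered the list and its mean was above 0 while the test pointed down.

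Other lists were not called after CLI. No gene changed among 25 mitotic genes (limma camera adjusted p = 0.0671), 20 NF-kB targets (0.834), 13 mitochondrially encoded transcripts (0.958), 9 luminal markers (0.958), 4 fibroblast markers (0.291) or 4 blood cell markers (0.637), each also with 0 adjusted over the list alone. Of 16 mesenchymal genes, SNAI1 rose from 5.1 ± 0.699 to 11.5 ± 0.382 CPM and LOX from 109 ± 2.34 to 145 ± 8.16 CPM (SD, n = 3 each; for LOX edgeR adjusted p = 0.0661 with the block within the 6 libraries), with 3 higher and 2 lower adjusted over the list alone (limma camera adjusted p = 0.278). Of 21 invasion genes, PTGS2 rose from 8.26 ± 1.06 to 18.1 ± 1.52 CPM, and the collagenase gene MMP1 fell from 265 ± 5.22 to 204 ± 10.2 CPM (edgeR adjusted p = 0.00263), with 2 higher and 4 lower adjusted over the list alone (limma camera adjusted p = 0.834). Of 21 immediate early genes, 2 were higher and 2 lower, 3 and 4 adjusted over the list alone (limma camera adjusted p = 0.291). JUNB among them rose by 0.41, with an adjusted p of 0.0509 without ERβ1 replicate 1 and 0.0809 with the block within the 6 libraries. IER3 rose by 0.18 and FOSL1 and DUSP5 fell by 0.22 each, with adjusted p of 0.0709, 0.1 and 0.0722 in edgeR with the replicate block and up to 0.171 without ERβ1 replicate 1 (IER3), 0.134 without ERβ1 replicate 2 (FOSL1) and 0.145 without ERβ1 replicate 1 (DUSP5). In 22 hypoxia genes P4HA1 alone was called, higher by 0.27 (edgeR adjusted p = 0.00475, and 0.0979 with the block within the 6 libraries), with 1 higher and 2 lower adjusted over the list alone (limma camera adjusted p = 0.067). In 25 cholesterol genes TM7SF2 rose by 0.82 (edgeR adjusted p = 0.0115, 0.0509 without ERβ1 with CLI replicate 1 and 0.131 with the block within the 6 libraries) and ACAT2 fell by 0.22 (0.0722 with the replicate block), with 1 higher and 3 lower adjusted over the list alone (limma camera adjusted p = 0.108). Single calls also stood in the lists of fatty acid genes (GPAM at 0.43, 16 genes, camera adjusted p = 0.534), p53 genes (CDKN1A at 0.22, 20 genes, 0.764) and epithelial genes (TJP1 at 0.21, 16 genes, 0.958), all higher, with adjusted p of 0.0639, 0.0503 and 0.0722 in edgeR with the replicate block. Adjusted over the list alone, 1, 1 and 2 members of these lists were higher. Single libraries also ended the calls of GPAM and CDKN1A (adjusted p up to 0.0909 and 0.0614, without ERβ1 replicate 2), TJP1 (0.12, without ERβ1 replicate 1) and ACAT2 (0.138, without ERβ1 with CLI replicate 3). No Wnt target (10 genes, camera adjusted p = 0.291) and no aryl hydrocarbon receptor target (8 genes, 0.215) was called, though 1 lower and, in the second list, 2 higher and 1 lower were adjusted over the list alone. In the lists of p53, epithelial, invasion, immediate early and mitochondrially encoded genes the median and mean differed in sign, and for luminal markers the mean of 0.03 and the downward test did.

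**Figure D3:**
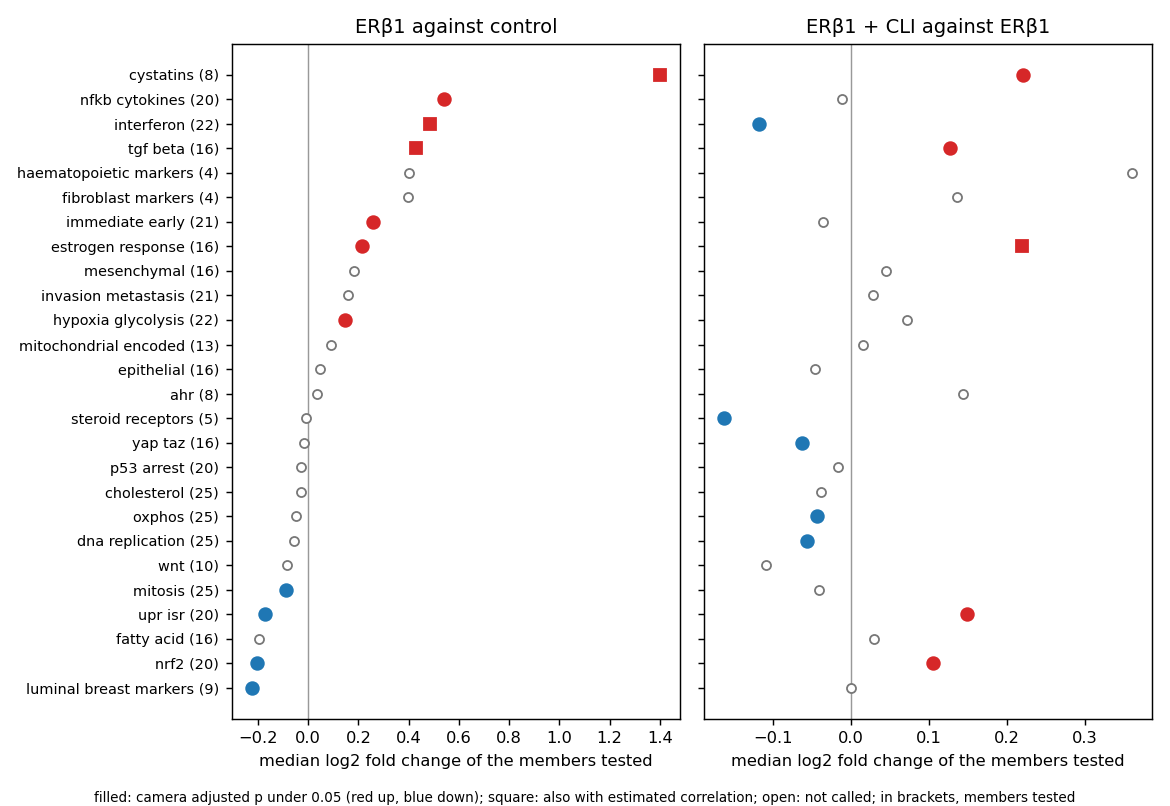
Median log2 fold change of the tested members of each gene list in ERβ1 cells against control (left) and in ERβ1 cells with CLI against ERβ1 cells (right), on separate scales. Filled symbols mark lists called by limma camera, 11 on the left and 10 on the right, and squares those that also held with an estimated correlation, 3 on the left and 1 on the right.

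The third comparison set ERβ1 cells with CLI against control cells and holds the effects of receptor and ligand together with other differences between the cell populations. Among genes named by the rule with a mean of at least 2 CPM, ESR2 apart, C3, OLFML3, GREB1, CCN5 and FABP3 rose most, by 5.33, 4.94, 4.85, 4.71 and 4.38 on the log2 scale, and ADAMTS1, LYPD5, ROBO1, CPVL and PAGE5 fell most, by 5.08, 4.35, 4.06, 3.76 and 3.28. The falls of ROBO1 and CPVL were -5.23 without ERβ1 with CLI replicate 3 and -4.59 without ERβ1 with CLI replicate 1. In this comparison 4512 genes changed (edgeR's quasi-likelihood test), 2274 upward and 2238 downward, and 814 changed at least 2-fold, 632 of them upward. The groups did not overlap for 7106 genes, where chance gives 10%, or 1705.8. Mitotic genes were lower in 15 of 25 cases, 17 adjusted over the list alone (limma camera adjusted p = 0.000212, but adjusted p = 0.378 with an estimated correlation), with CDC20 at -0.51 and TPX2 at -0.16. Oestrogen-responsive genes, cystatins, TGF-beta targets and interferon-stimulated genes were higher as groups, with limma camera adjusted p of 0.000457, 3.13e-07, 0.000384 and 2.66e-05, and 0.0387, 0.0274, 0.0387 and 0.0387 with an estimated correlation. Called higher were 7 of 16, 7 of 8, 9 of 16 and 11 of 22 members of these lists, and 7, 7, 9 and 14 adjusted over the list alone. NF-kB targets and hypoxia genes were also called higher (limma camera adjusted p = 8.49e-07 and 0.00458), and replication, respiratory and luminal genes lower (0.0138, 0.0088 and 0.00311), but with an estimated correlation their adjusted p were 0.246, 0.206, 0.466, 0.378 and 0.0691. The call of replication genes also ended without control replicate 2, with an adjusted p of 0.0586. Stress response genes were not called (limma camera adjusted p = 0.812), with 7 higher, among them SEL1L at 0.63 and HSP90B1 at 0.50, and 9 lower, among them PSAT1 at -0.53. The remaining lists were not called either, with limma camera adjusted p between 0.0545 for immediate early genes and 0.844 for epithelial genes, and the median and mean differed in sign for steroid receptor, p53 and epithelial genes.

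Against control, the same genes largely moved with and without CLI. Of 17058 genes, 2977 were called in the same direction in both groups of ERβ1 cells, 1474 higher and 1503 lower. Independent lists of these sizes give 482.1 (243.3 higher and 238.8 lower), a value that takes no account of the shared controls. The 20 simulations of unchanged groups called 0 genes without and on average 0.1 with CLI. Their overlap of 0 was therefore given in advance and is no measure of what the shared controls add. The 3 control libraries could not be split into sets of at least 2 each, so part of the excess in these counts may come from the shared controls. Across genes, which are not independent replicates, the covariance of the fold changes was 0.377, with 0.0491 in the simulations and a difference of 0.328.

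Most genes that rose with CLI were already higher in ERβ1 cells than in control. Of the 178 genes higher with CLI, 118 were also higher in ERβ1 cells than in control, 17 were lower and 43 were not called, where independent lists give 19.0 genes higher in both. GREB1, C3, PDZK1, FABP3, CCN5, PTGS2 and SNAI1 rose in both steps. INHBB and SLC47A1 were not called in ERβ1 cells against control, and HSPA5 was lower there by -0.14. Of the 73 genes lower with CLI, 23 were higher in ERβ1 cells than in control, 21 were lower and 29 were not called, with 7.81 and 7.79 in independent lists. These values take no account of the shared ERβ1 libraries, which on their own favour genes higher in 1 comparison and lower in the other. The transduced gene ESR2 is among the 23. IFIT1 and IFIT2 were among those that were higher in ERβ1 cells than in control and fell with CLI. Across all genes the covariance of receptor and ligand fold changes was -0.0321, with -0.0481 in simulations of unchanged groups (range -0.0553 to -0.0429), which is negative because both comparisons share the ERβ1 libraries with opposite sign. The observed value lay 0.016 above the simulated one. With single libraries left out the covariance was -0.135 to -0.0484, each time below the simulated mean for all 9 libraries. The simulations were not repeated with a library left out, so whether the direction holds there cannot be told. The covariance was -0.135, -0.126 and -0.118 without ERβ1 replicate 1, 2 and 3, and -0.0718 without ERβ1 with CLI replicate 2.

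**Figure D4:**
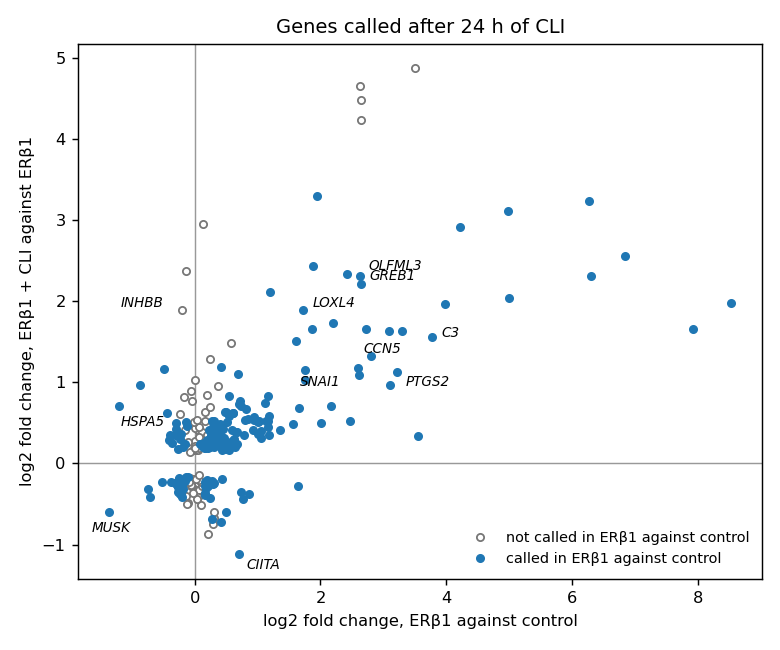
Log2 fold change of ERβ1 cells with CLI against ERβ1 cells (vertical axis) and of ERβ1 cells against control (horizontal axis) for the genes called after CLI, ESR2 left out. Filled dots were also called against control, among them the 118 genes higher in both comparisons in the upper right, and open dots were not.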

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

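The settings with receptor libraries numbered 1 and 3, the block within 6 libraries and the left-out windows were chosen only after the result was seen. Of 257 named gene results, 191 kept direction and call in all settings in which the gene was tested, 66 lost a call in at least 1 and 0 reversed. Not every gene was tested in each setting, with 251 results under the filter of at least 1 CPM and 240 with the windows left out. Of 31 list results, 8 kept their call in all settings run for lists. The count of genes in ERβ1 cells against control was 2517 to 3649 with 1 library left out and 2230 with the block within the 6 libraries. The counts of at least 2-fold changes against control were 395 and, with CLI, 499 under the filter of at least 1 CPM, which tests fewer genes of low counts. For ERβ1 cells with CLI against ERβ1 cells the count of genes was 583 with DESeq2, 158 with the 6 libraries alone, 114 to 211 with 1 library left out, 72 with numbers 1 and 3 only, 136 with the replicate block and 66 with the block within the 6 libraries. Single values without ERβ1 replicates 1, 2 and 3 were 117, 123 and 119, and without ERβ1 with CLI replicates 1 and 2 they were 153 and 150. Its count of at least 2-fold changes was 78 with DESeq2, 27 to 42 with 1 library left out, and 22 both with numbers 1 and 3 only and with the block within the 6 libraries. Its count of lists was 6 to 11 with 1 library left out and 6 with the block within the 6 libraries. With an estimated correlation the lists called were 3, 1 and 4 in the 3 comparisons, and with fry 21 in each comparison with control. The covariance of receptor and ligand fold changes was -0.453 with DESeq2, -0.119 with numbers 1 and 3 only, and -0.135 to -0.0484 with 1 library left out, with -0.126, -0.118 and -0.0718 without ERβ1 replicates 2 and 3 and ERβ1 with CLI replicate 2. Beyond the filter and the smaller number of libraries, the cause was not tested. For named genes of ERβ1 cells with CLI against ERβ1 cells, the replicate block over all 9 libraries changed no other call than those given in the report, and against control, where the numbers did not pair the samples, it ended 3 calls without and 1 with CLI. Of simulated changes of 1.25-fold, 18 and 20% were recovered, so most changes of that size were missed in the simulations. These called 118 and 122 genes, so their shares need not hold for ERβ1 cells against control, where 3645 genes were called. What depth alone limits was not tested.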

Other observations

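All gene families in this paragraph and the next were chosen only after the result was seen, and were tested with limma camera and adjusted over 9 families. In ERβ1 cells against control, 6 of 13 keratins were higher and 1 lower (camera adjusted p = 0.000319, but adjusted p = 0.0759 with an estimated correlation), with the hair keratin genes KRT81 and KRT86 at log2 fold changes of 1.64 and 1.15. Of 17 cytosolic tRNA synthetases, 9 were lower and 0 higher (0.000545, but adjusted p = 0.0759 with an estimated correlation), among them NARS1 at -0.46 and AARS1 at -0.39. Of 30 collagens, 9 were higher and 2 lower (0.0105, but adjusted p = 0.194 with an estimated correlation), with COL7A1 at 0.87 and COL4A4 at 1.52. Antigen presentation genes were higher in 8 of 23 cases (0.0138, but adjusted p = 0.144 with an estimated correlation), among them HLA-DRB1 at 0.60 and CD74 at 0.41.

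Circadian clock genes were higher in 6 of 21 cases and lower in 2 in ERβ1 cells (camera adjusted p = 0.0264, but adjusted p = 0.194 with an estimated correlation), with NR1D1 at 1.36 and BHLHE40 at 1.03. Ribosomal protein and proteasome genes were slightly lower (0.00265 and 0.0411, but 0.515 for both with an estimated correlation), and complement genes and histones were not called (0.0997 and 0.171). With CLI against ERβ1 cells, antigen presentation genes were lower (0.00414, but 0.156 with an estimated correlation) and histones higher (0.00565, but 0.279), with 1 gene called in each. Ribosomal protein and proteasome genes were lower there too (0.0163 and 0.0464, but 0.62 for both with an estimated correlation), with 0 genes called. Clock genes were not called there (0.0748), although ARNTL rose by 0.53 and BHLHE40 by 0.52.

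The test of reads left out of the counts and both tests on ESR1 below were chosen only after the result was seen. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05, and the real split was the largest, 1 of 10, in each case. The real counts of genes called were 3645, 251 and 4512 in the 3 comparisons and the highest of the other splits 1, 6 and 0. Counts of at least 2-fold changes were 626, 43 and 814 against 1, 4 and 0, and lists called were 11, 10 and 10 against 4, 4 and 3. For ERβ1 cells with and without CLI, the other splits that part all 3 pairs called 0, 1 and 0 genes.

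Neighbouring genes in 17 windows of 10 Mb differed between control cells and both groups of ERβ1 cells. GC content and transcript length do not explain it, since all 17 stayed past the threshold after their trends were removed, and nor does chance placement, since 1000 shuffles of gene positions gave at most 2 windows. A different number of chromosome copies in the transduced cells could give such runs: in windows chosen on every second gene, 85.4% of 362 held-out genes moved in the direction of their window, against 58% in other windows. No DNA was measured, and the design does not separate copies gained or lost during transduction and selection from an effect of the receptor over whole regions.

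ESR1 had 6.12 CPM in ERβ1 with CLI replicate 2, 0.768 CPM in ERβ1 with CLI replicate 1 and at most 0.125 CPM in any other library. Luminal breast cells mixed into the library are argued against by the 3 markers that are low elsewhere, whose summed rise was 4.4% of that of ESR1. These markers were FOXA1, TFF1 and TFF3, with 11, 9 and 1 counts in that library. Reads of the transduced ESR2 counted as ESR1 are argued against by the ratio of ESR1 to ESR2 counts, which was 72.3 times the median of the receptor libraries. The source of these reads stays open, and no biological explanation was tested.

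The libraries numbered 2 of both ERβ1 groups lay apart from those numbered 1 and 3, with 37 genes that differed between replicate numbers (edgeR). Depth is argued against, since 37 genes also differed after the 6 libraries were thinned to equal totals. Across all genes above 1 log2 CPM, GC content and length explained 2.93% of the variance of the deviation of the libraries numbered 2. That argues against them for the deviation at large. It cannot decide for the 37 genes, which are a small part of the genes in that variance. In both libraries numbered 2, 36 genes were lower than in those numbered 1 and 3, all but PLA2G12A, which was apart in those numbered 1; SMOX, for example, stood at 110 and 108 CPM in ERβ1 replicates 1 and 3 and 13.2 CPM in replicate 2. The transcripts AL162151.2, AL645608.5 and TGFB2-OT1 had 0 counts in both libraries and 5.14 to 22.4 CPM in the other 7. Reads of some transcripts left out of the counts of these 2 libraries could give such falls, and 37 genes lay below the mean of their group in both, but they were picked for a difference between numbers, so this cannot be told apart from a shared culture or preparation, and no biological explanation was tested.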
